A study of Mus musculus with 6 samples.

How the data were processed

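RNA was measured on 6 single-colour Affymetrix mouse arrays, 2 for each of 3 groups of E14Tg2a mouse embryonic stem cells. Per the labels' protocols, RNA was purified on silica columns, copied from an oligo-dT primer and labelled with biotin by in vitro transcription. The design text names the smaller A version of the mouse array, while the 45101 probe sets of the table and their annotation are those of its larger whole-genome version. The deposited values are probe set intensities on a linear scale, given as whole numbers from 6 to 26405, with a value for every probe set on every array. RMA, a method that corrects background, normalizes probes by quantiles and summarises each probe set, is named in the submitters' processing notes, with no version. The software, and whether other arrays were normalized together with these 6, are not given in the sources used here. RMA gives log2 values, so the deposited intensities had been returned to a linear scale and rounded, which makes steps of the dimmest values coarse. The medians of the 6 columns differ, from 37 to 49.

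Each intensity was converted to log2 and no further normalization was applied. The 64 Affymetrix control probe sets were left out of the tests, leaving 45037. Of these, 34945 have 1 gene symbol in the platform annotation, 932 have several and 9160 have none. The Entrez identifiers of 34741 were found in a table of RefSeq genes, which changed 0 symbols. No gene was named from a probe set with several symbols or none. Where 1 value per gene was needed, the probe set with the highest mean over the 6 arrays stood for the gene, which gave 18193 genes.

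Groups were taken from the sample titles. The title of 1 inhibitor array and the condition label of both spell the compound SB432542, and the source names and treatment protocol spell it SB431542, which is used throughout. A free-text number in the labels (such as control 2 for the first control) differs from the number in the title, and the title's number was used. The labels do not say whether the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. No vehicle is stated for the control cells. The numbers 1 and 2 of the titles were not used to pair arrays.

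All 6 arrays were fitted together in limma 3.58.1 (R 4.3.3) with 1 mean per group and eBayes at its default settings. Residual degrees of freedom were 3 and the prior added 2.51. P-values were adjusted by Benjamini-Hochberg over the 45037 probe sets, with a threshold of 0.05. The comparisons were activin against control, SB431542 against control, and activin against SB431542. Beside each count stands the count with an intensity trend in the prior variance and robust estimation, here called the intensity trend, because it moved every count of calls by over 1.5 times. This alternative was chosen before the data were examined, as were the main test, the gene lists and the naming rule. The residual SD of the arrays follows the level, with a median of 0.077 in the brightest of 10 equal bins of probe sets and 0.35 in the most variable bin.

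The 19 gene lists held 352 entries, of which 328 matched a named probe set. The other entries were not analysed here. Each list was tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 19 lists of a comparison. Camera with an estimated correlation and fry were run beside it.

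Genes were named by a fixed rule. In each comparison with control these were the 12 largest rises and 12 largest falls among probe sets past the threshold whose 2 treated values lay on 1 side of both control values, and 8 each way between the treatments. Where fewer than 5 qualified, the smallest p-values in that direction filled the list to 5, given as values that did not pass. Members of the fixed lists past the threshold and a set of 14 pathway and pluripotency genes with a named probe set were always given. Genes named for passing with the intensity trend, and 4 examples with the smallest p per list, were chosen after their values were seen.

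The correlation and covariance of the 2 treatments' log2 fold changes were set against 100 simulated draws of unchanged groups sharing the control arrays. The arrays give no detection call. Their background is described by 27 probe sets for unspiked Bacillus transcripts, with log2 values from 3.00 to 5.09 and a median of 3.52. Precision is limited by the number of arrays.

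The fit was tested on 5 simulated sets of 45037 probe sets, with 200 changed in each in the SB431542 against control comparison. The default setting recovered 0.00% of changes of 1.5-fold, 6.00% of 2-fold, 46.4% of 4-fold and 67.2% of 8-fold changes, and 2.29% of its calls were false. The intensity trend recovered 4.40%, 21.2%, 60.4% and 82.4%, with 1.86% of calls false. These rates include dim probe sets. Among probe sets with a mean over log2 8 the default setting recovered 0.00%, 11.5%, 87.9% and 95.4% of the same folds. The intensity trend recovered 20.4%, 78.8%, 100% and 100% of them. The list test recovered a shift of 0.5 log2 units in 5 of 5 sets with 0 other lists called. Genes were simulated independently of each other and without shifts of whole arrays. These sets therefore cannot show false calls, of probe sets or lists, that come from correlation between genes or from such shifts. The shares of false calls above may not hold for the real arrays. In the real arrays the estimated correlation was 0.391 for mesendoderm genes.

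Alternatives left out each array in turn, used the replicate number as a block, left out the dimmest 40% of probe sets, repeated quantile normalization, shifted columns to 1 median, fitted only the 4 arrays compared, added 32 before the log, required 1.5-fold, used an adjusted p of 0.10, or kept 1 probe set per gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.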

Results

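Gene expression was measured in E14Tg2a cells, a feeder-independent mouse embryonic stem cell line, grown in the serum-free medium N2B27 with BMP4 at 20 ng/ml and LIF at 1000 U/ml. Cells were left untreated, given activin at 10 ng/ml for 2 h, or given SB431542 at 5 µM for 24 h. Activin is a ligand that signals through the same receptors and Smad2/3 proteins as Nodal, and SB431542 inhibits the kinase of those type I receptors. Each group had 2 arrays. The median intensity was 46 and 37 on the control arrays, 38 and 49 on the activin arrays, and 43 and 41 on the SB431542 arrays. The first principal component, with 30.9% of the variance, placed the SB431542 arrays at 38.6 and 42.5, the controls at −34.1 and −24.8, and the activin arrays at −9.24 and −12.9. The second, with 25.6%, parted arrays within the control and activin groups. It ordered the 6 arrays as their median intensities do, from −37.1 for the control array at 37 to 42.6 for the activin array at 49.

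The comparison of SB431542 with control asked which transcripts depend on any Activin/Nodal signal present in cultures without added activin. The deepest falls were in Lefty1 and Lefty2, secreted Nodal antagonists that are themselves induced by Nodal. Lefty2 went from a log2 intensity of 8.95 ± 0.01 (SD, n = 2) in control to 3.90 ± 0.14, a log2 change of −5.05 (SE 0.13, limma adjusted p = 0.0030). Lefty1 went from 10.68 ± 0.14 to 5.14 ± 0.63, a change of −5.53 (SE 0.30, limma adjusted p = 0.034). Both ended at or near the level of the unspiked bacterial probe sets, so their folds are limited by background. Eomes, a T-box factor of early mesendoderm and trophoblast, fell by 2.32 (SE 0.14, limma adjusted p = 0.046), while its second probe set was at −1.15 and did not pass (limma adjusted p = 0.225). Psmb8, an immunoproteasome subunit, fell by 2.60 (SE 0.12, limma adjusted p = 0.021). Ascl2, a basic helix-loop-helix factor needed in the trophoblast lineage, rose by 2.03 on the log2 scale (SE 0.12, limma adjusted p = 0.046), 4.09-fold.

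**Figure D1:**
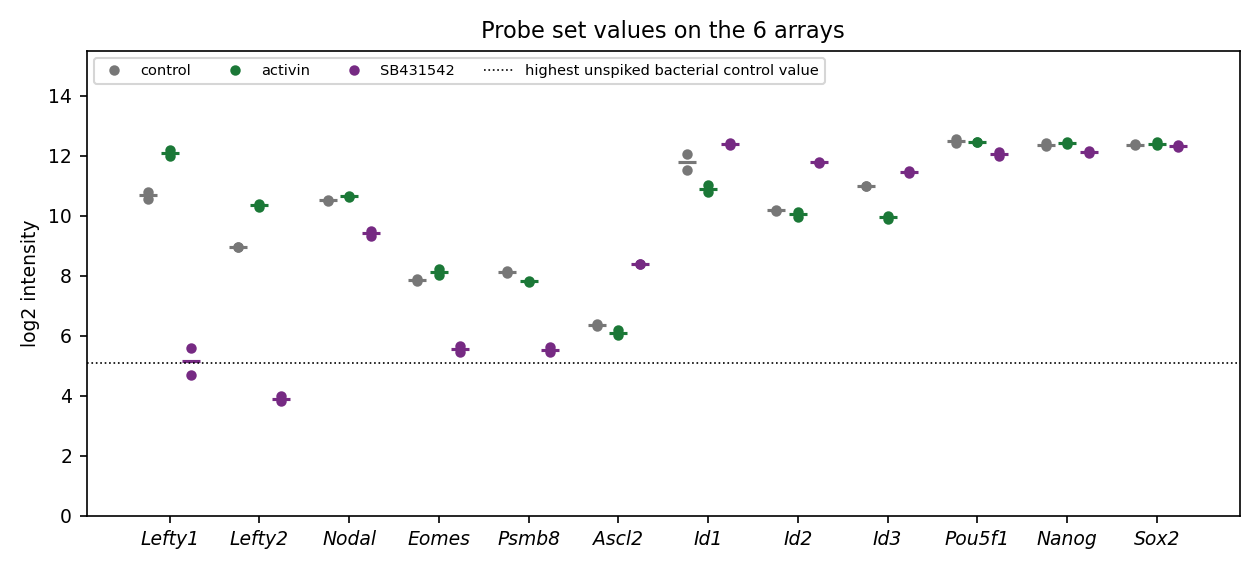
Log2 intensity of 12 genes on each of the 6 arrays, 1 probe set per gene. Points are arrays, short lines are group means and the dotted line is the highest unspiked bacterial control value, 5.09. Lefty2 lies at 3.90 after SB431542 and at 10.34 after activin, while Sox2 has a mean between 12.33 and 12.40 in each group.

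In all, 7 of 45037 probe sets passed, 1 higher and 6 lower, and 2 of the lower ones carry no gene symbol. With the intensity trend 2242 passed, 1520 higher and 722 lower, among them the same 7. Leaving out each of the 6 arrays in turn, the default test called 0 every time, while the intensity trend called 947 without SB431542 replicate 1 and 1217 without SB431542 replicate 2. The balance of directions depended on the controls, with 1667 higher and 422 lower without control replicate 1, and 1032 higher and 929 lower without control replicate 2. The genes nearest the default threshold in the rising direction were Id2, at +1.60 (adjusted p = 0.098), Gm12108 at +1.72, Kctd1 at +1.47 and a Gata2 probe set at +2.77. A brighter Gata2 probe set gave +0.95, and a second Id2 probe set +0.73 (adjusted p = 0.184). Trim67, at −2.28 (adjusted p = 0.098), was nearest among those lower.

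The list of Nodal/Activin target genes fell as a group (camera adjusted p = 4.57e-10, and adjusted p = 0.229 with an estimated correlation). All 14 measured members were below control, 2 fell over all probe sets, 9 fell adjusted over the list alone and 8 with the intensity trend. Nodal itself was at −1.10 (SE 0.13), Fgf8 at −2.45 (SE 0.24), Pmepa1, an inhibitor of Smad2/3 signalling, at −0.99 (SE 0.17) and Smad7, an inhibitory Smad, at −0.66 (SE 0.17). Fgf8 ended at a log2 intensity of 4.22, within the range of the unspiked bacterial probe sets, so its fold is limited by background. Skil, a Smad co-repressor, was at −0.41 (SE 0.12). Components of the pathway, 18 genes for receptors, Smads and ligands, had a median of 0.01 and did not pass (camera adjusted p = 0.959).

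Mesendoderm genes also fell as a list (camera adjusted p = 1.05e-05, and adjusted p = 0.430 with an estimated correlation), with Eomes called over all probe sets, 8 of 18 lower and 1 higher adjusted over the list alone, and 5 lower with the intensity trend. Mixl1, a homeobox gene of the primitive streak, was at −2.63 (SE 0.27). Primed epiblast genes fell (camera adjusted p = 0.0077, and adjusted p = 0.430 with an estimated correlation), with 3 of 14 lower adjusted over the list alone. Fgf15 was at −1.84 and Fgf5 at −1.27, while Otx2 was at +0.43 and Dnmt3b at +0.13. Fgf5 had a mean log2 intensity of 5.13 in control and 3.85 after SB431542. The highest unspiked bacterial value was 5.09, so Fgf5 stood at or under background in both groups. Cer1, at −0.74, went from 4.83 to 4.09, under that value in both groups. Fgf15, Fgf5 and Cer1 were the 3 members counted as lower. Wnt/beta-catenin-responsive genes fell (camera adjusted p = 0.0090, and adjusted p = 0.430 with an estimated correlation), with 3 of 13 lower adjusted over the list alone. Sp5, at −1.55, and Notum, at −1.05, led this list, and Axin2 was at −0.14. The lists that fell share members, so their calls are not independent of each other. Fgf8 is among both the Nodal/Activin targets and the mesendoderm genes, and Cer1 is in both of those lists and the primed epiblast list. Cdx1 is in the mesendoderm and Wnt lists. The primed epiblast list missed the threshold without control replicate 2 (camera adjusted p = 0.0881).

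Trophectoderm genes rose as a list (camera adjusted p = 6.18e-09, and adjusted p = 0.243 with an estimated correlation). Of 16 members, Ascl2 rose over all probe sets, 12 rose and 1 fell adjusted over the list alone, and 11 rose with the intensity trend. Gata3 was at +1.29 (SE 0.32), Esx1 at +1.18 (SE 0.15) and Hand1 at +1.09 (SE 0.17), and the simple-epithelium keratins Krt8 and Krt18 were at +0.43 and +0.46. Cdx2, a factor of the early trophectoderm, was at −0.11 (SE 0.29). BMP target genes rose (camera adjusted p = 1.30e-05, and adjusted p = 0.243 with an estimated correlation), with 0 of 17 called over all probe sets, 11 higher and 1 lower adjusted over the list alone and 8 higher with the intensity trend. Besides Id2, an inhibitor of basic helix-loop-helix factors, Id4 was at +0.94, Msx2 at +0.88, Smad6 at +0.70, Id1 at +0.60 and Id3 at +0.48. Hand1 and Dlx3 are in both lists. Immediate early genes rose (camera adjusted p = 8.17e-04, and adjusted p = 0.430 with an estimated correlation), with Ccn1 at +1.25 and Atf3 at +1.17 but Myc at −0.58 and Ier2 at −0.42.

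**Figure D2:**
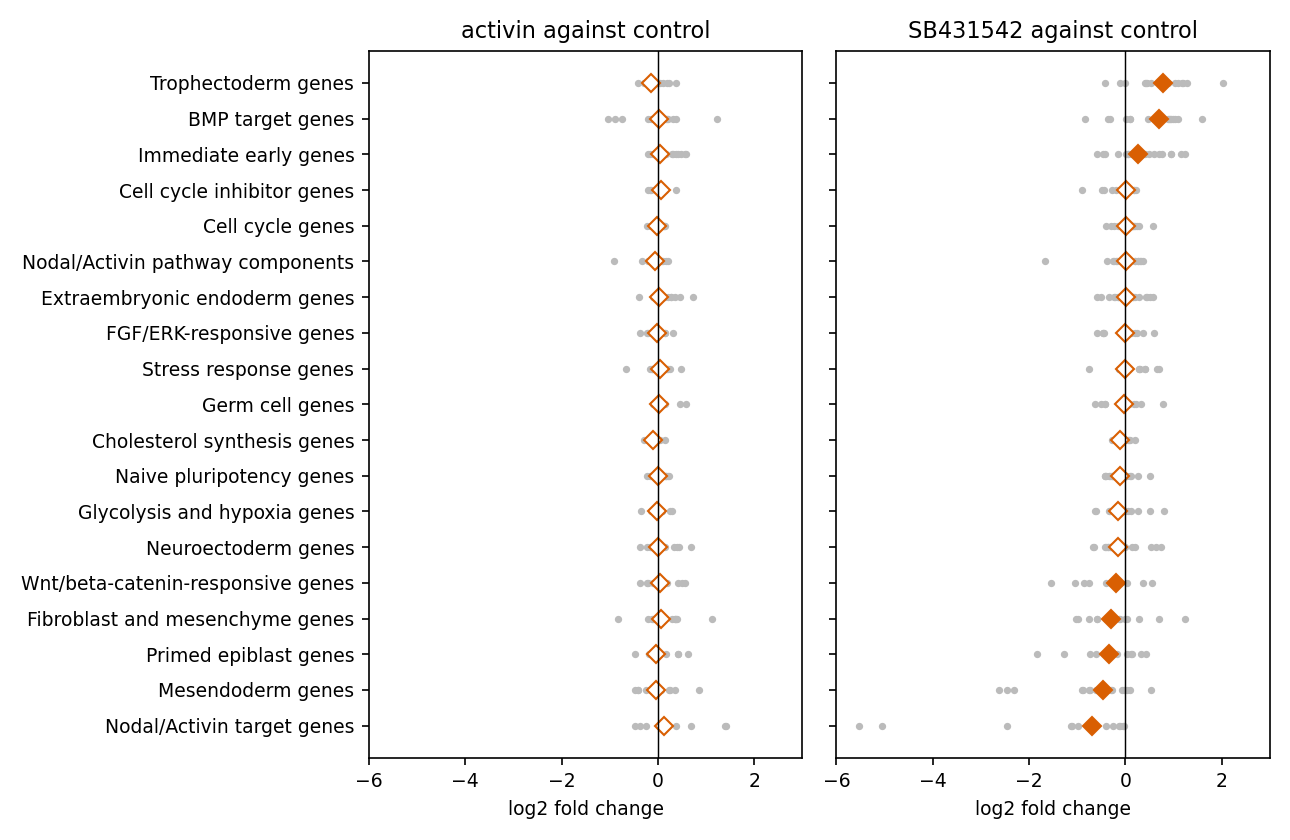
Log2 fold changes against control of the members of the 19 gene lists (grey points, 1 probe set per gene) and their medians (diamonds, filled where the list passed camera at an adjusted p of 0.05), for activin on the left and SB431542 on the right. The medians after SB431542 run from −0.70 for Nodal/Activin targets to 0.78 for trophectoderm genes, and 0 lists passed by default after activin.

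Core pluripotency genes had small log2 changes, none past the default threshold. Pou5f1 was at −0.43 (SE 0.13, limma adjusted p = 0.308), Nanog at −0.24 (SE 0.12, limma adjusted p = 0.463) and Sox2 at −0.05 (SE 0.12, limma adjusted p = 0.897). With the intensity trend Pou5f1 and Nanog passed, with adjusted p = 1.51e-04 and 0.0408. The 25 naive pluripotency genes had a median of −0.11 and did not pass by default (camera adjusted p = 0.0511). With an intensity trend in camera the list fell (adjusted p = 0.0070), with 6 members lower and 1 higher by that setting, and with an estimated correlation it did not pass (adjusted p = 0.430). Among markers of other cells, the fibroblast and mesenchyme list fell (camera adjusted p = 0.0217, and adjusted p = 0.430 with an estimated correlation), with 4 members lower and 1 higher adjusted over the list alone. Lox, a matrix cross-linking enzyme, was at −1.02, Col1a1, a fibrillar collagen chain, at −0.98, Cdh2 at −0.75 and Vim at −0.58, and Ccn1, a secreted matrix protein also among the immediate early genes, was at +1.25. The list missed the threshold without control replicate 1 (0.0630), control replicate 2 (0.0629) or SB431542 replicate 1 (0.129). Extraembryonic endoderm, neuroectoderm and germ cell genes did not pass, with camera adjusted p = 0.679, 0.150 and 0.679. Nor did cell cycle genes (0.589), cell cycle inhibitors (0.379), cholesterol synthesis (0.200), glycolysis and hypoxia (0.351), stress response (0.326) or FGF/ERK-responsive genes (0.679).

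The comparison of activin with control asked how the cells respond to 2 h of added activin. Lefty2 was 2.63-fold higher, at 10.34 ± 0.07 (SD, n = 2) against 8.95 ± 0.01, a log2 difference of +1.39 (SE 0.13). Lefty1 was at +1.42 (SE 0.30), Pmepa1 at +0.70 (SE 0.17) and Smad7 at +0.38 (SE 0.17), with a second Smad7 probe set at +0.82. Nodal was at +0.14 (SE 0.13) and Skil at +0.13. In the other direction, Id3 was at −1.04 (SE 0.12), from 10.99 ± 0.00 to 9.94 ± 0.06, and Id1 at −0.90 (SE 0.21). Id2 was at −0.14, and a second Id2 probe set at −0.64. Smad6 was at +0.21, and Pou5f1, Nanog, Sox2 and Fgf5 lay between −0.04 and 0.05.

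By limma at its default settings 0 probe sets passed, with 2797 at an unadjusted p under 0.05 where 2252 are expected by chance, and a smallest adjusted p of 0.789. With the intensity trend 97 passed, 88 higher and 9 lower. Of the genes above, Lefty2 (adjusted p = 2.03e-06), Pmepa1 (0.0349) and the second Smad7 probe set (0.0016) rose by that test, Id3 (2.36e-09) and the second Id2 probe set (0.0011) fell, and Lefty1 (0.341) and Id1 (0.194) did not pass. Spsb1 also rose by that test, by 0.88 on the log2 scale, and Anp32a fell by 1.15. Leaving out either control array or either activin array changed both the total and the number lower, so neither count is settled. Higher probe sets stayed the more numerous each time, least clearly without control replicate 2. The other smallest default p-values were those of Gm12108 (+1.78), Parp3 (+1.45), Fsd2 (+1.14) and Tifa (+1.07) among higher genes, and of Prmt7 (−1.25), 4930473H19Rik (−1.04), Terb2 (−0.86) and Rbfox1 (−0.86) among lower genes. The control means of those 4 higher genes, from 4.13 to 4.83, lie below the highest unspiked bacterial value of 5.09, so their folds are limited by background.

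None of the 19 lists passed after activin by default. With an intensity trend in camera 3 passed, Nodal/Activin targets higher (adjusted p = 2.36e-04), immediate early genes higher (0.0457) and cholesterol synthesis genes lower (0.0457). With an estimated correlation none of them passed (adjusted p = 0.879 for each). By default the Nodal/Activin targets came nearest, with a median of 0.14 and 11 of 14 members above control (camera adjusted p = 0.120), and 3 rose adjusted over the list alone. BMP targets had a median of 0.02 and a mean of −0.03 (camera adjusted p = 0.648), with 3 lower adjusted over the list alone. The adjusted p of the other 17 lists lay between 0.224 and 0.851.

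The direct comparison of activin with SB431542 shares no control array and tests whether the 2 treatments differ, at durations of 2 h and 24 h. Lefty2 was higher after activin by 6.44 log2 units (SE 0.13, limma adjusted p = 7.78e-04) and Lefty1 by 6.95 (SE 0.30, limma adjusted p = 0.016). Fgf15, a ligand of the FGF family, was higher by 2.47 (SE 0.15, limma adjusted p = 0.037), with Eomes higher by 2.56 and Psmb8 by 2.27. Ascl2 was lower by 2.28, a value of −2.28 (SE 0.12, limma adjusted p = 0.025). In all 9 probe sets passed, 8 higher and 1 lower, of which 3 higher ones have no gene symbol, and 1024 passed with the intensity trend, 361 higher and 663 lower. Below the threshold were Id2 at −1.74 (adjusted p = 0.066), Id3 at −1.52 (0.073), Sh3bp5 at −2.18 and Nap1l3 at −1.56. Leaving out any 1 of the 6 arrays lost every default call. With the intensity trend lower probe sets stayed the more numerous each time, least clearly without activin replicate 1. The size of their excess thus depended on the arrays kept, and its direction did not.

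Between the treatments 10 lists passed, 7 higher and 3 lower after activin. Nodal/Activin targets were higher (camera adjusted p = 1.37e-12), as were mesendoderm (3.65e-06), Wnt/beta-catenin-responsive (6.36e-05), fibroblast and mesenchyme (3.80e-04), primed epiblast (0.0021), naive pluripotency (0.0150) and neuroectoderm genes (0.0273). Trophectoderm (2.62e-11), BMP target (2.77e-06) and immediate early genes (0.0103) were lower. With an estimated correlation the smallest adjusted p was 0.166 and 0 lists passed. Without activin replicate 1 the naive pluripotency (0.310) and neuroectoderm (0.131) lists missed the threshold, without activin replicate 2 the immediate early list (0.0706), and without SB431542 replicate 2 the neuroectoderm list (0.125). The neuroectoderm list also missed it with the intensity trend (0.0598), repeated quantile normalization (0.0807) and columns shifted to 1 median (0.127), and the naive pluripotency list with columns shifted (0.208) and with a gene's probe sets averaged (0.125).

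**Figure D3:**
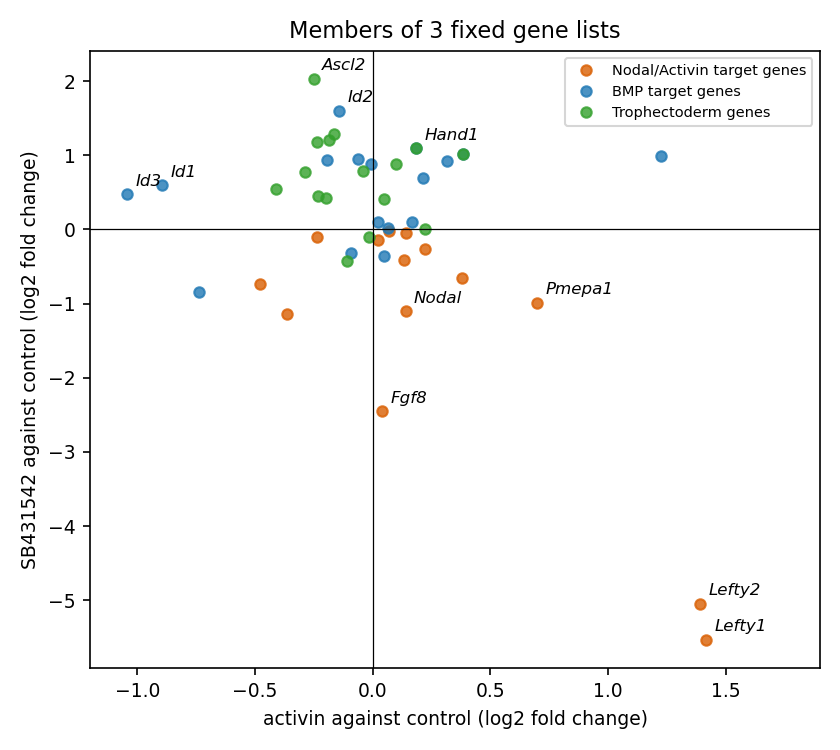
Log2 fold change against control after activin (horizontal) and after SB431542 (vertical) for the members of 3 gene lists, 1 point per gene. Lefty1 and Lefty2 lie at the lower right, with 1.42 and 1.39 after activin and −5.53 and −5.05 after SB431542, and Id1 and Id3 at the upper left.

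The 2 sets of changes against control were also set against each other, since the treatments act on the same receptors in opposite senses. Lefty2, Pmepa1 and Spsb1 rose after activin and fell after SB431542 by the intensity trend, and Id3 fell and rose. These were 3 genes where 0.558 are expected for independent lists, and 1 where 0.0850 is expected. These counts use the brightest probe set of each gene, by which 25 genes were higher after activin, while 73 had any probe set higher. Of the 25, 20 were higher after SB431542 too, where 1.06 are expected, among them Map3k12, Tra2a, Rad21 and Mcl1. Across 18193 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.466, where unchanged groups sharing the control arrays gave 0.4998, with a range of 0.480 to 0.520. The covariance was 0.0396 against 0.0227 simulated (range 0.0216 to 0.0243), and 67.2% of genes had the same sign against 66.6% (range 66.0 to 67.5). Against their simulated ranges, r lay below, the covariance above and the shared sign within. These positions need not conflict, since r divides the covariance by the spread of both sets of changes, and a wider spread lowers it. With 2 control arrays no split left 2 for each treatment, so part of the overlap may come from the shared controls.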

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

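The intensity trend alone, robust estimation alone, both with the dimmest 40% of probe sets left out, crossed pairing, and leaving out arrays under the intensity trend were chosen after seeing the data. The degrees of freedom of the variance prior were 2.51 by default and 34.3 with the intensity trend and robust estimation. They were infinite with columns shifted to 1 median, which adds the same offset to bright and dim probe sets. Every probe set was then tested with 1 common SD of 0.269. Before the shift the median residual SD was 0.35 in the most variable bin, and it was not computed after the shift. Counts with columns shifted may therefore be too liberal for the more variable probe sets. In activin against control, the default 0 became 97 with the intensity trend and robust estimation, 78 with columns shifted to 1 median (40 higher, 38 lower), 4 with the trend alone and 104 with trend, robust estimation and the dimmest 40% left out. The other settings gave 0.

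In SB431542 against control, 7 became 2242 with the intensity trend and robust estimation, 1200 with the trend alone, 2457 with trend, robust estimation and the dimmest left out, 791 with columns shifted (427 higher, 364 lower), 163 with 32 added (99 higher, 64 lower), 40 with quantile normalization repeated (18 higher, 22 lower), 21 with the dimmest left out, and 16 at an adjusted p of 0.10. All 7 remained in each of these. With robust estimation alone 5 passed, 0 higher and 5 lower, and Ascl2 and Eomes missed the threshold. With 1 probe set per gene 5 passed, since the 2 without a symbol were not tested. In activin against SB431542, 9 became 1024, 434, 1189, 412 (204 higher, 208 lower), 88 (47 higher, 41 lower), 49 (30 higher, 19 lower), 30 and 31 under the same settings in that order, with all 9 kept, and 19 with 1 probe set per gene, which tests fewer. With only the 4 arrays compared, and so fewer residual degrees of freedom, both counts were 0. Leaving out any 1 array gave 0 calls by default in each comparison; a lone array was taken to vary like the other groups. With the intensity trend these counts ran from 21 to 201 for activin, 947 to 2560 for SB431542 and 402 to 1493 between the treatments.

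The replicate numbers did not pair the arrays: deviations of equal numbers correlated at −0.141 between control and activin, 0.022 between control and SB431542 and −0.093 between activin and SB431542. With the replicate block 0, 0 and 1 probe sets passed in the 3 comparisons, and 0, 8 and 10 lists. A crossed pairing of control and activin gave 0.

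The list calls after SB431542 numbered 8 by default and 0 with an estimated correlation, and 3 with fry, which asks whether a list's genes move and does not compare them with other genes. Between the treatments 10 became 0 and 4. After activin 0 became 3 with the intensity trend and 1 with the dimmest left out, columns shifted, 32 added or a gene's probe sets averaged. The correlation of the 2 treatments' changes, 0.466, was 0.435 without the dimmest 40%, and ran from 0.5895 to 0.5945 without 1 control array, where a single shared array carries more of the noise. Uncalled activin values near 0 turned sign: with columns shifted Nanog was at −0.0150, Sox2 at −0.0409 and Fgf5 at −0.0290, and with quantile normalization repeated Fgf5 was at −0.0382. Without 1 array Pou5f1 ran from −0.115 to 0.0432, Nanog from −0.00129 to 0.101, Sox2 from −0.0294 to 0.0773 and Fgf5 from −0.231 to 0.303. Except where named, the cause of a change was not tested. Probe sets near background, at log2 values up to 5.09, limit the size of any fold, upward or downward.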

Other observations

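Of the tests below, those on array background, on other lineages, on dim probe sets, on fibroblast transcripts and on splits of the arrays were chosen after the result was seen, and those on the shared controls and on further interferon-inducible genes before. The tests on other lineages, which at first included mesendoderm genes, on dim probe sets, on fibroblast transcripts and on array background were each revised after a first version had been computed, those on other lineages and dim probe sets more than once.

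Several genes known to be induced by interferon, chosen after their values were seen, had low values after SB431542. Besides Psmb8, the immunoproteasome subunit Psmb10 was at −1.64 (SE 0.13), the interferon-inducible GTPase Irgm1 at −1.51 (SE 0.19), the antigen-trimming peptidase Erap1 at −1.68 (SE 0.24), Rtp4 at −2.23 (SE 0.27), Ifi35 at −1.13 (SE 0.14) and the transcription factor Irf1 at −0.84 (SE 0.12). Each of these passed with the intensity trend and, apart from Psmb8, not by default. The class I genes H2-K1 and H2-D1 were at +0.10 and +0.39, and B2m at −0.08. Over 52 measured interferon-inducible genes, these included, 15 fell with the intensity trend and 0 rose, and camera gave p = 0.128 with an estimated correlation. Cxcl10 was at +0.71 and Stat2 at +0.34.

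A candidate explanation of the low interferon genes is that a few were picked by eye from a long list. Against this, 29 measured interferon-inducible genes whose values had not been looked at also lay lower (camera p = 5.47e-04, 22 of 29 below control, median −0.24), though only 2 of them, Parp9 and Dtx3l, passed singly with the intensity trend, 19 had a control level under log2 6, and p was 0.264 with an estimated correlation. Less RNA from fibroblasts may also lower such genes, and the labels name no feeder layer. The fibroblast transcripts Col1a2, Col3a1, Postn and Dcn had a mean control level of 4.91 and lay between 4.41 and 6.00, where the highest unspiked bacterial control was at 5.00, which leaves this open. A response of these genes to the inhibitor, or to the 24 h of treatment, was not tested apart.

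For the rise of trophectoderm and BMP target genes after SB431542, a smaller share of stem cells with more differentiated cells of every kind might account for it. Members of the extraembryonic endoderm and neuroectoderm lists did not follow, with list medians of 0.004 and −0.16. The trophectoderm median exceeded that of their pooled members by 0.861, where that difference had an SD of 0.0286 between replicate arrays. It was 0.882 and 0.879 on the SB431542 arrays, and −0.113 and −0.182 on the activin arrays. Genes of a list are not independent, so no p-value over genes is given. The high trophectoderm median and the results of both other lists were known when this test was chosen. The gap therefore describes these lists and does not exclude a smaller share of stem cells. Probe sets near background might also give a rise. The 10 members with a level over log2 8 on the activin arrays, which this comparison does not use, argue against that for themselves, with a median of 0.538 (median SE 0.145) and 7 that rose with the intensity trend. The other 21 had a median of 0.768, but only 16 of them lay above the highest bacterial control value on both control arrays, which leaves background open for the dimmer members. A smaller share of stem cells, a greater response to the BMP4 in the medium when Activin/Nodal signalling is blocked, and a larger share of trophoblast-like cells stay open. No test here decides between them.

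For the changes that both treatments share against control, chance values of the 2 control arrays remain a candidate cause. With a different control array for each treatment the covariance was 0.0116 or 0.0125, within the bound of 0.0153. That bound was set beforehand at 4 times 0.00383, the largest covariance of replicate deviations between groups, and the smaller value was 3.03 times it, so the choice of multiple decides the outcome. Over all genes, with both controls shared, the covariance was 0.0396, above the simulated maximum of 0.0243. The simulated noise was independent between genes with a pooled SD, so it may not match the noise of the 2 control arrays. For that reason the excess decides nothing. The correlation lay below its simulated range and the shared sign within it, but the correlation is also lowered by a wider spread of changes in either treatment. A difference in background between arrays could also add to the covariance. Over 6493 genes with a mean level over log2 8 the covariance was 0.0157 against at most 0.0108 in simulated unchanged groups, a simulated bound that excludes nothing by itself. Handling that was common to both treated groups cannot be told apart from a shared response, since the labels name no batch or vehicle.

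With the intensity trend, 97 probe sets parted activin from control, and the highest count among the other splits of those 4 arrays was 2. For SB431542 and control the counts were 2242 and 0. The real split was in each case the 1 of 3 with the most, and 3 splits are too few for a share under 0.05. Each other split also mixed treated and control arrays within its groups. Any treatment difference then added to the residual spread, which lowers those counts, so they do not show what unchanged arrays would give.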
